A study of Mus musculus with 6 samples.

How the data were processed

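RNA was extracted with Trizol from CD8 T cells in 3 samples from MondoA-floxed mice without Cre (WT) and 3 samples from such mice with CD4cre (KO), and libraries were made with a Vazyme mRNA kit, per the labels' protocols. The deposited table holds whole-number read counts per Ensembl gene, not normalized, with 1 column for each of the 6 samples. For these counts by the authors, the submitters' processing notes name the GRCm39 assembly, the aligner HISAT2, and Subread with its read counter featureCounts. The versions, the annotation release, the aligner settings, the strand setting and the treatment of reads with several positions are not given in the sources used here. Because the strand setting is not known, reads of overlapping and antisense genes cannot be told apart, and near-identical gene copies can share or lose reads.

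The table had 57010 gene identifiers, of which 52029 took a symbol by exact match of the Ensembl identifier to GENCODE M21 on GRCm38. That annotation was used for names, transcript length and GC content, and because its assembly differs from that of the counts no coordinates are given. Of the genes tested 426 had no symbol. Samples were grouped by the genotype in their labels.

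Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 16439. Libraries were scaled by TMM, and KO was compared with WT by edgeR's quasi-likelihood test (glmQLFit, glmQLFTest, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes belong to the same fit. Values per sample are TMM-scaled CPM, given as mean ± SD, and the fitted fold change need not equal the ratio of the printed means. The common biological coefficient of variation was 0.166. The median standard error of a log2 fold change was 0.113 for the 9866 genes at a mean of at least 5 CPM. An exact permutation test of 3 samples against 3 cannot go below p = 0.1, so per-gene tests rest on the model's sharing of spread over genes. A count of 0 allows 3 counts, and such limits cover counting error only.

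Gene lists were tested with camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists of at least 3 tested genes, and again with an estimated correlation and with fry. Camera asks whether the genes of a list rank higher or lower than all others, whereas fry tests the genes of a list on their own. The lists covered MondoA targets, the MYC, MAX and MLX network, metabolic pathways, T cell states, proliferation, stress, and markers of CD8 T cells, other cell types and sex. Some genes stand in more than 1 list. Members of a list were also adjusted over the list alone. For the NK, glycolysis, hypoxia, interferon, cholesterol and naive and memory lists the median log2 fold change was also taken after removal of a trend with log2 transcript length, GC content and mean log2 CPM, fitted over all tested genes by natural splines, with a bootstrap interval over the genes of the list. Bootstrap intervals here take genes as independent and hold none of the spread between samples, so they do not test an effect of genotype.

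Genes are named by this rule: Mlxip, Mlx, Mlxipl, Txnip and Arrdc4 always, then the 10 largest changes in each direction among called genes with a mean of at least 5 CPM and groups that do not overlap, the 5 of smallest p in each direction, and from each list up to 4 members of smallest p, or at most 2 where no member passed. For marker lists up to 3 of the most abundant members were added. Predicted models, pseudogenes and antigen receptor segments were left out of the rule. Pgk1, Dntt, the cytokine and activation genes other than Ccl4 and Gzma, and the genes named for a single alternative or split fall outside the rule and were chosen after their values were seen.

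No pair of replicates matched within sampling noise. Over 12176 genes with a mean of at least 50 counts the chi-square per gene was between 16.0 and 40.2 within groups. The 10 most abundant genes took between 4.52% and 4.68% of the counts of a library, and mitochondrially encoded genes between 1.68% and 1.94%.

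The procedures were tested on simulated counts with the real means and library sizes of KO against WT. Each run had 200 changed genes, in a step over 15993 genes. The changed genes were drawn from those at a mean of at least 5 CPM, with changes from 1.41-fold to 8-fold. The quasi-likelihood test recovered 37.5% of 1.41-fold changes, 80% of 1.68-fold changes and 96% of 2-fold changes. Over 5 runs it made 50 false calls and DESeq2 made 155. With fewer true changes the adjusted threshold is stricter, so these shares do not give the power in the real data or for scarcer genes. With nothing changed, 6 genes and 0 lists were called over 5 runs of 16439 genes. A glycolysis list raised by 0.5 on the log2 scale was called in 5 of 5 runs, and in 4 of 5 with an estimated correlation. Simulated genes were drawn independently of each other, whereas the interferon list had an estimated correlation of 0.839 in the real data. The runs therefore do not measure false list calls among genes that move together.

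The alternatives tried were other scalings (RLE size factors, library size only), no filter and a filter at a mean of 5 CPM, DESeq2, limma-voom, a robust edgeR fit, the replicate number as a block, a minimum absolute log2 fold change of 1, a prior count of 0.5 for the lists, each library left out in turn, and a term for sex. The sex term set apart libraries with over 1000 Xist reads and was added after the data were seen.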

Results

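Gene expression was measured by RNA sequencing in mouse CD8 T cells with and without a CD4cre-driven deletion of MondoA, the glucose-sensing transcription factor encoded by Mlxip. Naive CD8 T cells came from the spleen and lymph nodes of C57BL/6 mice aged 8 weeks and were stimulated through CD3 and CD28 for 24 hours. The 3 WT libraries came from mice with the floxed gene and no Cre, and the 3 KO libraries from mice with the floxed gene and CD4cre, a transgene active in developing T cells. Total gene counts were 34010820, 32089316 and 26150420 in WT 1 to 3, and 32089885, 33848339 and 34447230 in KO 1 to 3. A gene without a read in the shallowest library, WT 3, could have stood at up to 0.115 CPM there (counts scaled to the library's total), a limit of 3 counts that covers counting error only. The labels number the replicates and do not say that each came from its own mouse, so the p-values measure the spread between these 6 samples, part of which may be technical.

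The comparison of KO with WT asks which transcripts differ with the deletion of MondoA in activated CD8 T cells. Cre was present in KO alone, so an effect of Cre cannot be told apart from one of MondoA loss. Nor can effects of the deletion in developing T cells be told apart from effects in the activated cells. Mlxip itself (ENSMUSG00000038342) was measured first, as a check of the labels. It stood at 129 ± 11.1 CPM (SD, n = 3) in WT and 86.0 ± 6.54 CPM (SD, n = 3) in KO, a log2 fold change of -0.58 with a standard error of 0.0921, and the 3 KO libraries lay below the 3 WT libraries. Counts were summed over the whole gene, and the labels do not name the deleted exons, so the KO value does not show how complete the deletion was. Over all 16439 genes tested the edgeR quasi-likelihood test gave Mlxip a Benjamini-Hochberg adjusted p of 0.125, which missed the threshold. Adjusted over the list alone, among the 10 tested genes of the MYC, MAX and MLX network, its p was 0.000793 by the same edgeR test with Benjamini-Hochberg adjustment. Without a filter on low counts, with DESeq2, or with a term for the sex of the mice added after the data were seen, Mlxip passed over all genes, with log2 fold changes of -0.58, -0.57 and -0.58. The counts were the same in each, so these calls are not independent of each other.

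The direct targets Txnip and Arrdc4 fell steeply in the KO cells. Txnip (ENSMUSG00000038393) encodes the thioredoxin-interacting protein, an arrestin-family protein that limits glucose uptake. It went from 222 ± 9.32 CPM (SD, n = 3) in WT to 76.6 ± 3.40 CPM (SD, n = 3) in KO, a log2 fold change of -1.53 (standard error 0.0792). Arrdc4 (ENSMUSG00000042659), a related arrestin-domain gene, went from 32.1 ± 4.20 CPM (SD, n = 3) to 3.74 ± 0.759 CPM (SD, n = 3), a log2 fold change of -3.10 (standard error 0.173). Their adjusted p-values were 3.85e-05 for Txnip and 4.07e-05 for Arrdc4 (edgeR quasi-likelihood test, Benjamini-Hochberg), and in both genes all 3 KO libraries lay below all 3 WT libraries.

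**Figure D1:**
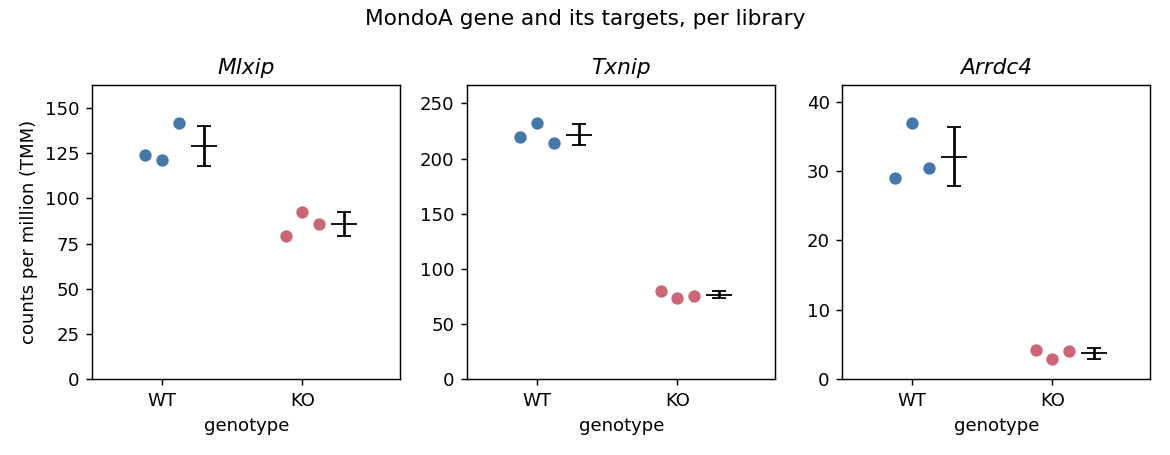
CPM (read counts scaled to library size with TMM factors, y axis) of Mlxip, Txnip and Arrdc4 in each of the 3 WT (blue) and 3 KO (red) libraries, with the mean and SD of each group in black beside its points. Group means were 129 and 86.0 CPM for Mlxip, 222 and 76.6 CPM for Txnip, and 32.1 and 3.74 CPM for Arrdc4, and no KO library reached a WT library in any of the 3 genes.

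Txnip and Arrdc4 were the only 2 genes past an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 0 higher and 2 lower in KO. At an unadjusted p under 0.05 there were 1778 genes, 830 higher and 948 lower, where chance alone gives 822. Other splits of the 6 libraries into 3 and 3 gave from 219 to 1748 such genes. This excess therefore does not by itself show an effect of genotype. The groups did not overlap for 2704 genes, 16.4% of those tested, against 10% by chance. DESeq2 called 153 genes, 87 higher and 66 lower, 17 of them with an absolute log2 fold change of at least 1. Without a filter on low counts edgeR called 511, and without KO 3 it called 80, of which 65 were higher. Both Txnip and Arrdc4 were among the genes called in each of these settings.

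**Figure D2:**
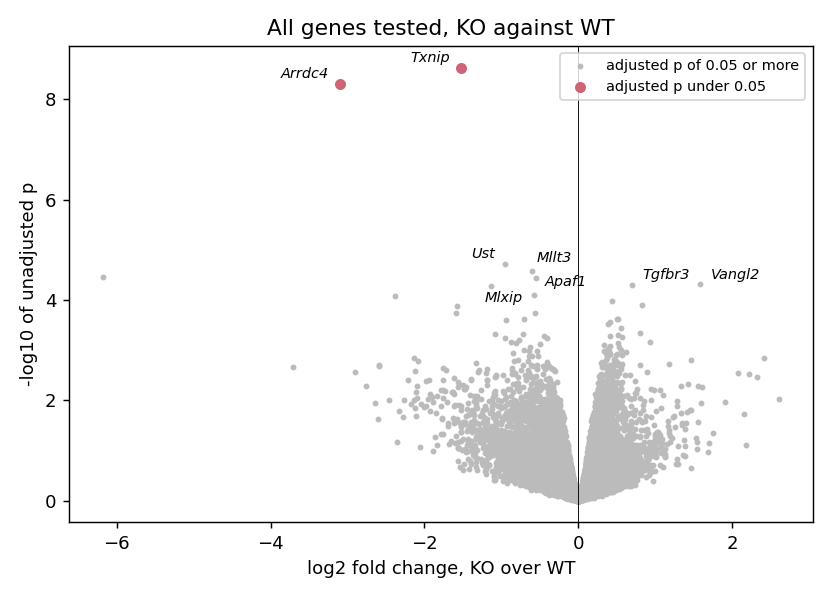
Log2 fold change of KO over WT (x axis) against the -log10 of the unadjusted p (y axis) for the 16439 genes tested, 1 point per gene, with the 2 genes past an adjusted p of 0.05 in red. Txnip and Arrdc4 stand apart from all other genes, Mlxip and 5 other genes of small p are labelled, and the leftmost grey point is an immunoglobulin V segment.

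The other tested members of the MondoA network did not pass over all genes. Of the 4 listed MondoA targets all were lower in KO, but only Txnip and Arrdc4 passed. Arrdc3 had a log2 fold change of -0.032 and Klf10, a TGF-beta inducible zinc finger gene, of -0.20. As a group the list passed camera at the preset correlation (camera adjusted p = 0.000269, adjusted p = 0.298 with an estimated correlation) and also passed fry, with an adjusted p of 0.00018. Txnip and Arrdc4 make up 2 of its 4 genes, so these list tests give no separate evidence for Arrdc3 and Klf10. Mlx, which encodes the obligate DNA-binding partner of MondoA, was 21.1 ± 0.543 CPM (SD, n = 3) in WT and 22.3 ± 3.65 CPM (SD, n = 3) in KO, a difference within the spread of the replicates. The paralogue Mlxipl (ChREBP) had 2, 6 and 0 reads in WT and 0, 6 and 0 reads in KO, too few to test. Across the 10 tested genes of the wider network 5 were higher and 5 lower (camera adjusted p = 0.775), and only Mlxip passed when adjusted over the list alone. Max, the shared partner of the MYC family, had a log2 fold change of 0.21 and did not pass.

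Apart from Txnip and Arrdc4, the genes of smallest p in each direction did not pass over all genes in the edgeR quasi-likelihood test. Ust, which encodes a sulfotransferase acting on glycosaminoglycans, went from 156 ± 16.0 to 81.0 ± 13.5 CPM (SD, n = 3 each), a log2 fold change of -0.95. Mllt3, a reader of acylated histones, had a log2 fold change of -0.61. Apaf1, the core of the apoptosome, had -0.55. On the other side, the planar cell polarity gene Vangl2 went from 1.30 ± 0.0667 to 3.90 ± 0.638 CPM (SD, n = 3 each), a log2 fold change of 1.58. Tgfbr3, a TGF-beta co-receptor, had a log2 fold change of 0.70. The edgeR quasi-likelihood test gave these 5 genes a Benjamini-Hochberg adjusted p of 0.0960 each. Tdrp (0.44), the gut-homing receptor gene Ccr9 (0.83) and the kinase-like gene Peak1 (0.50) followed, in log2 fold change, with adjusted p of 0.141, 0.155 and 0.206 by the same edgeR test with Benjamini-Hochberg adjustment. All 8 genes passed with DESeq2 and in edgeR without a filter on low counts, 6 passed without KO 3 (not Tdrp and Peak1), and Ust and Mllt3 passed with the sex term added after the data were seen. These settings reuse the same counts and give no independent support.

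Gene lists were then compared as groups. Of 37 lists tested with camera at a preset inter-gene correlation of 0.01, 21 passed, 12 higher and 9 lower in KO. With the correlation estimated from these libraries 0 of the 37 passed, the smallest adjusted p being 0.298. Fry, which asks whether the genes of a list move on balance one way, passed 2 lists, the MondoA targets and cholesterol synthesis. Outside the MondoA targets no member of any list passed over all genes by edgeR. Such members did pass without a filter on low counts (61 higher and 40 lower), without KO 3 (25 higher and 3 lower, 23 of them interferon-stimulated genes), with DESeq2 (10 higher and 9 lower) and with the sex term added after the data were seen (Mlxip alone, lower). The lists are therefore reported as wholes, and the log2 fold change or level of each named member is given without a call. With library size as the only scaling several small medians moved by over 1.5 times, to 0.067 for the respiratory chain, 0.041 for the TCA cycle, 0.084 for glutamine use, 0.095 for heat shock, 0.059 for the unfolded protein response, -0.18 for cholesterol synthesis and -0.19 for p53 genes.

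The glycolysis and hypoxia lists stood higher in KO by camera at the preset correlation. Of the 24 glycolysis and glucose transport genes 18 were higher and 6 lower, with a median log2 fold change of 0.25 (camera adjusted p = 1.98e-05, adjusted p = 0.401 with an estimated correlation). Adjusted over the list alone 7 rose and 0 fell, against 0 over all genes by edgeR and 3 by DESeq2. The glycolysis list's median deviation from the mean of the 6 libraries was -0.091, -0.16 and -0.10 in WT 1 to 3. It was 0.17, 0.21 and -0.0042 in KO 1 to 3, so KO 3 lay nearest to WT. Tpi1, triosephosphate isomerase, was 151 ± 7.50 CPM in WT and 223 ± 34.8 CPM in KO (SD, n = 3 each). Eno1, enolase, was 931 ± 33.8 CPM in WT and 1207 ± 123 CPM in KO (SD, n = 3 each). The hypoxia and HIF1 list had 16 genes higher and 8 lower (median 0.23, camera adjusted p = 0.00224, adjusted p = 0.298 with an estimated correlation). The 3 of its genes that rose when adjusted over the list alone, Tpi1, Ldha and Pgk1, are glycolytic enzymes held by both lists. After removal of a trend with transcript length, GC content and expression level the median was 0.15 for glycolysis (bootstrap interval 0.10 to 0.23) and 0.13 for hypoxia (bootstrap interval -0.041 to 0.27, which includes 0). The pentose phosphate list did not pass (camera adjusted p = 0.0573, Tkt 0.28 in log2 fold change), except without WT 2 (0.0236) or KO 3 (0.0231).

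The respiratory chain and TCA cycle lists were also higher in KO on average, by smaller medians. Their median deviations were 0.25 and 0.16 in KO 1. KO 2 (-0.020 and -0.039) and KO 3 (-0.026 and -0.0089) lay below WT 2 (0.036 and 0.056). Of 52 nuclear-encoded respiratory chain genes 48 were higher (median 0.13, camera adjusted p = 1.98e-05, adjusted p = 0.619 with an estimated correlation), with Atp5a1 at 0.22 (0.14 without KO 1) and Cyc1 at 0.20. Of 22 TCA cycle genes 16 were higher (median 0.11, camera adjusted p = 0.0262, adjusted p = 0.619 with an estimated correlation), among them Cs at 0.23. Without KO 1 the respiratory chain list had an adjusted p of 0.156 and a median of 0.046, and the TCA list an adjusted p of 0.449 and a median of 0.037, by camera. The TCA call was also lost without WT 1 (camera adjusted p = 0.0605), without WT 3 (0.276, median 0.057), with library size as the only scaling (0.0908) and at a mean of at least 5 CPM (0.127). Glutamine transport and use had 9 of 11 genes higher (median 0.15, camera adjusted p = 0.0167, adjusted p = 0.342 with an estimated correlation), led by Oat at 0.32 and Slc38a2 at 0.19, and gave a camera adjusted p of 0.0683 without WT 1 and 0.0564 without KO 1. The mitochondrially encoded genes (median 0.10, camera adjusted p = 0.0573, mt-Co3 at 0.57) and fatty acid oxidation (camera adjusted p = 0.125) did not pass. The mitochondrially encoded list did pass camera without a filter on low counts (adjusted p = 0.0352), with the replicate number as a block (0.0481), without WT 1 (0.0106) and without KO 1 (0.00221), while its median was 0.016 without KO 3 and 0.036 with library size as the only scaling.

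Cholesterol synthesis moved the other way. Of 25 genes of the pathway and its SREBP2-driven neighbours 20 were lower and 5 higher, with a median log2 fold change of -0.11 (camera adjusted p = 0.00216, adjusted p = 0.298 with an estimated correlation), and the list passed fry with an adjusted p of 0.000802. Hmgcs1, which makes the precursor of mevalonate, was 79.6 ± 1.77 CPM in WT and 65.9 ± 1.27 CPM in KO (SD, n = 3 each). After removal of a trend with transcript length, GC content and expression level the median was -0.14 (bootstrap interval -0.22 to -0.025). Tm7sf2, a sterol reductase, had a log2 fold change of -0.42. The list's median deviation was above 0 in all 3 WT libraries and below 0 in all 3 KO libraries, at sizes between 0.0451 and 0.0761 in WT. Fatty acid synthesis did not pass (camera adjusted p = 0.788), with Scd1 at -0.68 (-0.38 without KO 3).

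Naive and memory T cell genes stood higher as a list. Of its 31 genes 28 were higher (median 0.21, camera adjusted p = 1.98e-07, adjusted p = 0.308 with an estimated correlation), and 6 rose when adjusted over the list alone, against 0 over all genes by edgeR and 3 by DESeq2, with Ccr9 and Nsg2 (0.46) at their head. Removal of a trend with transcript length, GC content and expression level left the list a median of 0.12 (bootstrap interval 0.027 to 0.21). All 17 CD8 T cell identity genes were higher (median 0.17, camera adjusted p = 1.98e-05, adjusted p = 0.454 with an estimated correlation). Among them Zap70, the kinase recruited to the T cell receptor, was at 0.28 and the receptor constant gene Trac at 0.25. Without WT 1 the identity list's median was 0.11, without WT 2 it was 0.25, and with library size as the only scaling it was 0.10. Thymocyte genes did not pass as a list (camera adjusted p = 0.125, but 0.0455 with library size as the only scaling), although Ccr9, Themis (0.47) and Dntt rose when adjusted over the list alone.

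Effector molecules stood lower. Of 25 cytokine, chemokine and cytotoxic genes 20 were lower and 5 higher (median -0.25, camera adjusted p = 0.00772, adjusted p = 0.308 with an estimated correlation). Gzma, granzyme A, was 29.5 ± 27.6 CPM in WT and 7.41 ± 1.68 CPM in KO (SD, n = 3 each), and Ccl4 had a log2 fold change of -1.09. WT 3 held 61.1 CPM of Gzma against 17.3 and 10.1 CPM in WT 1 and WT 2, and without WT 3 its log2 fold change was -0.88 in place of -1.98. Without WT 3 the median of the list was -0.15, and with the genes limited to a mean of at least 5 CPM it was -0.12. Ifng, also of this list, did not share the fall. Without TMM scaling it was at 25.5, 56.9 and 15.4 CPM in WT 1 to 3 and at 78.6, 48.8 and 16.8 CPM in KO 1 to 3. The transcription factors of effector differentiation did not pass (camera adjusted p = 0.175, with Id2 at -0.57 and Gata3 at 0.41), except without WT 2 (0.0306) or KO 2 (0.0323). Activation markers (camera adjusted p = 0.876, Cd28 at 0.25 and Rel at -0.25) and inhibitory receptors (camera adjusted p = 0.728, Havcr2 at -1.32, or -0.76 without WT 3) did not pass either. Klrg1, a receptor of terminally differentiated effector cells, was the 1 inhibitory receptor that fell when adjusted over the list alone, from 1.65 ± 1.39 to 0.118 ± 0.154 CPM (SD, n = 3 each), with 3.21 CPM in WT 3 against 1.17 and 0.56 CPM in WT 1 and WT 2. Its log2 fold change was -3.71, and with 1 library left out it ran from -5.54 (without KO 3) to -2.81 (without WT 3).

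Interferon-stimulated genes were higher in 2 of the 3 KO libraries. Of 44 genes 41 were higher in KO on average (median 0.46, camera adjusted p = 2.12e-08, adjusted p = 0.619 with an estimated correlation), and 9 rose when adjusted over the list alone, against 0 over all genes by edgeR and 2 by DESeq2. Oasl2 was 563 ± 4.91 CPM in WT and 800.3 ± 161 CPM in KO (SD, n = 3 each), and Ifi27l2a had a log2 fold change of 0.56. The list's median deviation from the mean of the 6 libraries was 0.36 in KO 1 and 0.50 in KO 2 but -0.28 in KO 3, below the WT libraries at -0.21, -0.075 and -0.26. Without KO 2 the median of the list was 0.28. Without KO 3 it was 0.67, and 23 genes of the list then passed over all genes by edgeR, of the 65 called higher in that setting, with Irf7 (1.02), Isg15 (1.19) and Ifit1 (1.45) among them in log2 fold change.

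Growth and proliferation lists moved in both directions. All 37 ribosome biogenesis genes were higher on average (median 0.26, camera adjusted p = 1.39e-08, adjusted p = 0.619 with an estimated correlation), including Rrp12 at 0.56 and Wdr43 at 0.45, with a median of 0.15 and Rrp12 at 0.35 without KO 1. The list's median deviation was -0.18, 0.077 and -0.28 in WT 1 to 3. It was 0.36, 0.048 and -0.012 in KO 1 to 3, so WT 2 lay above KO 2 and KO 3. Heat shock and handling genes (17 of 20 higher, camera adjusted p = 0.00892, Dnajb1 at 0.53) and the unfolded protein response (18 of 21 higher, camera adjusted p = 0.0138, Calr at 0.36) passed, each with an adjusted p of 0.619 with an estimated correlation. Without KO 1 their camera adjusted p-values were 0.108 and 0.417, with medians of 0.097 and 0.046 in place of 0.16 and 0.13, and Calr was at 0.18. The heat shock list gave a camera adjusted p of 0.0651 without KO 2 and a median of 0.28 without KO 3, and the unfolded protein list gave 0.0613 without WT 1 and 0.0911 without WT 3. DNA replication had 32 of 45 genes higher (median 0.065, camera adjusted p = 0.0349, adjusted p = 0.619 with an estimated correlation), with Mcm5 at 0.35 (0.21 without KO 1) and Cdt1 at 0.27. That call was lost without WT 1 (camera adjusted p = 0.330, median 0.029), without KO 1 (0.400, median 0.025), with library size as the only scaling (0.0877, median -0.0030) and at a mean of at least 5 CPM (0.230, median 0.042). Mitosis genes were lower (33 of 38, median -0.18, camera adjusted p = 0.00441, adjusted p = 0.619 with an estimated correlation), with Nuf2 at -0.75 and Bub1b at -0.34. The mitosis call was lost without WT 3 (camera adjusted p = 0.485, median -0.070) and without KO 1 (camera adjusted p = 0.0849, median -0.10), and without WT 2 the median was -0.29.

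Of the p53 and apoptosis genes 18 of 24 were lower (median -0.12, camera adjusted p = 0.0262, adjusted p = 0.619 with an estimated correlation). Apaf1 fell when adjusted over the list alone, and Pmaip1, a BH3-only death gene, had a log2 fold change of -0.35. Leaving out KO 3 (camera adjusted p = 0.635, median -0.053), WT 1 (0.0605) or WT 2 (0.192) ended that call, as did the removal of the low-count filter (0.0993) and the sex term added after the data were seen (0.0561), whereas without KO 1 the median was -0.22. Redox genes did not pass (camera adjusted p = 0.941), but Srxn1, sulfiredoxin, fell when adjusted over the list alone, with a log2 fold change of -0.87. The amino acid stress list (camera adjusted p = 0.479, Slc3a2 at 0.33 and Phgdh at 0.41, or 0.27 without KO 1), autophagy and lysosome genes (camera adjusted p = 0.535, Ctsl at 0.32) and ribosomal proteins (camera adjusted p = 0.167) did not pass. The amino acid stress list did pass without KO 3 (camera adjusted p = 0.00968), and ribosomal proteins did without WT 1 (0.00680) and without KO 2 (0.0382).

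Lists of markers of several other cell types stood lower on average in the KO libraries, beside the lower effector list and the higher CD8 identity list. The counts do not show which cells held these transcripts, and some CD8 T cells share the NK receptors. By median deviation WT 2 (-0.34) lay below KO 2 (-0.074) and KO 3 (-0.21) in the myeloid list. In the B cell list WT 2 (-0.18) lay below KO 1 (-0.0048) and KO 2 (0.023). In the CD4 list WT 2 lay below KO 3 (-0.0077 against 0.020). NK and innate-like genes were lower in 13 of 15 cases (median -0.61, camera adjusted p = 0.000100, adjusted p = 0.308 with an estimated correlation), and 6 fell when adjusted over the list alone, against 0 over all genes by edgeR and 4 by DESeq2. Klrc2, an activating NKG2 receptor, was 6.78 ± 1.37 CPM in WT and 2.27 ± 0.692 CPM in KO (SD, n = 3 each), and Klre1 was 4.11 ± 0.942 CPM in WT and 1.36 ± 0.358 CPM in KO (SD, n = 3 each). The Klrc genes are close relatives, so reads can be split between them. The median of this list was -0.39 without KO 1, -0.32 without KO 2 and -0.96 without KO 3. Myeloid and dendritic cell genes were lower in 16 of 17 cases (median -0.64, camera adjusted p = 0.000930, adjusted p = 0.619 with an estimated correlation), with Cst3 at 119 ± 43.5 CPM in WT and 80.8 ± 21.5 CPM in KO (SD, n = 3 each). B cell genes were lower in 18 of 19 cases (median -0.45, camera adjusted p = 0.00224, adjusted p = 0.619 with an estimated correlation), with Cd74 at 137 ± 58.2 CPM in WT and 89.8 ± 15.2 CPM in KO (SD, n = 3 each), while Ighm was 237 ± 54.5 CPM in WT and 225 ± 19.2 CPM in KO (SD, n = 3 each). The B cell call was lost without WT 3 (camera adjusted p = 0.154) and without KO 3 (camera adjusted p = 0.139, median -0.28). All 8 CD4 and regulatory T cell genes were lower (median -0.42, camera adjusted p = 0.00570, adjusted p = 0.401 with an estimated correlation), with Cd4 at 3.71 ± 0.982 CPM in WT and 1.80 ± 0.701 CPM in KO (SD, n = 3 each), Foxp3 at -0.75 in log2 fold change, and a list median of -0.24 both without KO 1 and at a mean of at least 5 CPM. Without WT 3 the log2 fold change was -0.33 for Cst3 and -0.33 for Cd74, in place of -0.55 and -0.61, that of Cst3 was -0.35 without KO 1, and that of Foxp3 was -0.43 without WT 1. Erythroid and platelet (camera adjusted p = 0.369) and stromal genes (camera adjusted p = 0.480) did not pass.

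**Figure D3:**
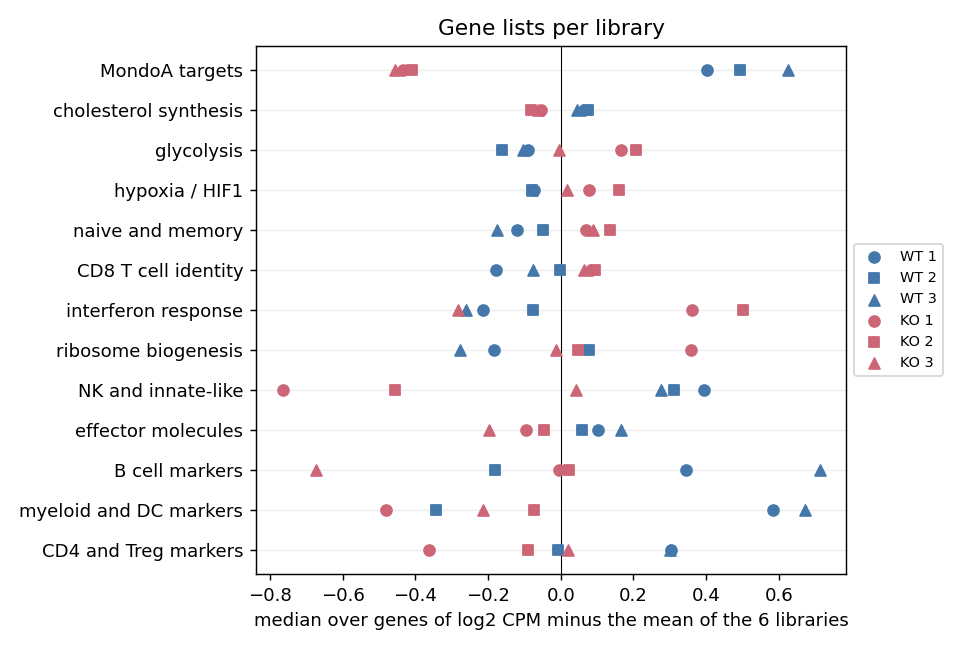
Median over the genes of each list of log2 CPM minus the mean of the 6 libraries (x axis), for 13 of the 37 lists (y axis), with 1 point per library, WT in blue and KO in red, and the replicate number given by the shape of the point. The MondoA targets, cholesterol synthesis, glycolysis, hypoxia, naive and memory, CD8 identity, NK and effector lists separate the groups, whereas KO 3 lies at -0.28 in the interferon list, below all 3 WT libraries.

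Sex differed within both groups. Xist, the transcript that silences one X chromosome, stood at 737 CPM in WT 3 and 668 CPM in KO 2, and at under 2 CPM in the other libraries, where the Y-linked genes were expressed. The sex-linked list did not differ between the groups by camera (adjusted p = 0.949). In 7 lists, none of which passed, the median, the mean and the direction of the test did not share a sign. These were thymocyte, autophagy, inhibitory receptor, fatty acid synthesis, activation, redox and sex-linked genes.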

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

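The alternatives were chosen before the data were examined, apart from the sex term. Txnip and Arrdc4 kept their direction and their call in every setting run, with log2 fold changes from -1.60 to -1.49 and from -3.21 to -2.94. The count of called genes was 2 with RLE factors, with library size only, at a mean of at least 5 CPM, with limma-voom, with the robust fit and at an absolute log2 fold change of at least 1. It was 511 without a low-count filter (245 higher, 266 lower), 153 with DESeq2 (87 higher, 66 lower, and 4463 genes without an adjusted p) and 6 with the sex term (0 higher, 6 lower: Txnip, Arrdc4, Ust, Mlxip, Lilr4b and Mllt3, of which Lilr4b can share reads with a near-identical copy). The cause of these differences between counts was not tested as such. Of the 511 genes called without the filter 34 had a mean under 1 CPM. Txnip had an unadjusted p of 7.88e-51 without the filter and 2.34e-09 with it (edgeR quasi-likelihood test). Its log2 fold change was -1.53 in both, and its standard error was 0.102 without the filter and 0.0792 with it. For Mlxip the standard error was 0.103 without the filter and 0.0921 with it. In these 2 genes neither a larger change nor a smaller standard error gave the smaller p, which leaves the degrees of freedom of the test. Calls without the filter are therefore not stronger evidence for a gene. Leaving out 1 library gave between 2 and 80 genes, 0 to 65 higher and 2 to 15 lower, the upper end without KO 3. The log2 fold change of Mlxip ranged from -0.65 to -0.51 over the alternatives. It passed at -0.577 without the filter, -0.570 with DESeq2 and -0.582 with the sex term, with adjusted p-values of 6.56e-06, 8.60e-05 and 0.0420 (edgeR quasi-likelihood test and DESeq2, Benjamini-Hochberg) against a range of up to 0.535.

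The replicate numbers gave no sign of pairing, since libraries of the same number had deviations that correlated at -0.00567, -0.189 and -0.0474. With so few libraries this cannot exclude a pairing that the labels do not state. With the replicate block 2 genes and 22 lists were called, the added list being the mitochondrially encoded genes. The number of lists called was 0 with an estimated correlation and 2 with fry, and 15 to 22 with 1 library left out. Scaling moved the median log2 fold change of all genes by at most 0.0662.

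Among the named genes that did not pass, 5 changes of sign came with a library left out. Mlx then ranged from -0.038 to 0.20, Klf10 from -0.37 to 0.052, Arrdc3 from -0.12 to 0.050 and Ighm from -0.19 to 0.12. Lists that did not pass also changed direction, given here as Benjamini-Hochberg adjusted p-values of camera or fry. At a mean of at least 5 CPM these were activation (0.706), autophagy (0.942), redox (0.424) and sex-linked genes (0.942). With library size only they were fatty acid synthesis (0.986) and redox (0.986), with RLE factors sex-linked genes (0.966), with the sex term activation (0.992) and sex-linked genes (0.184), and with fry activation (0.952), redox (0.838) and sex-linked genes (0.947). With 1 library left out the ranges were 0.181 to 0.825 for activation, 0.00968 to 0.876 for amino acid stress, 0.0919 to 0.968 for erythroid genes, 0.496 to 0.925 for the MLX network, 0.431 to 0.825 for redox, 0.00680 to 0.925 for ribosomal proteins and 0.308 to 0.848 for sex-linked genes.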

Other observations

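All tests of this part were chosen after the result was seen, except the counts over other splits of the samples and the tests for a trend with transcript length, GC content and expression level in the NK and glycolysis lists.

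Cytokine transcripts were uneven after 24 hours of stimulation. Il2, the growth factor of activated T cells, had 2 reads in all 6 libraries together and Il3 had 0, while Csf2 had 26 and Il21 had 20. The activation genes Cd69 (252 to 406 CPM over the libraries, without TMM scaling) and Il2ra (140.3 to 228 CPM) were abundant in both groups. Ifng was at 25.5, 56.9 and 15.4 CPM in WT 1 to 3 and at 78.6, 48.8 and 16.8 CPM in KO 1 to 3, so the groups overlapped. Tnf was between 24.3 and 29.4 CPM in WT and between 19.7 and 22.7 CPM in KO. Lta was between 28.7 and 39.3 CPM in WT and between 17.5 and 26.35 CPM in KO. Neither passed over all genes by edgeR, and groups failed to overlap for 16.4% of all genes tested.

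Antigen receptor segments went in both directions. Of 102 immunoglobulin V segments 88 were lower in KO, 17 of all 102 at an unadjusted p under 0.05, 0 past the adjusted threshold of the edgeR quasi-likelihood test and 1 past that of DESeq2. Of 84 T cell receptor V segments 59 were higher, 2 of all 84 at an unadjusted p under 0.05 and 0 past the adjusted threshold of either tool.

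The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For the genes, 2 of the 10 splits gave at least the real count of 2, and the highest other split called 3 (5830417I10Rik, Rps3a2, which has near-identical copies, and Rhob). That split sets WT 3, KO 2 and KO 3 against the rest and so holds both libraries of high Xist on one side. For the lists, 1 of the 10 splits, the real one, gave 21 or more, and the highest other split gave 18.

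NK receptor genes were lower in KO, by a list median of -0.61 over 15 genes, of which Klrd1 was the most abundant at 91.3 CPM in WT and 77.4 CPM in KO. NK cells carried over into WT stay open: Ncr1, Klra8 and Klra4 summed to only 2.18% of the fall in Klrc2 and Klre1 (3.60% at most when the spread of the fall is allowed for), but they had 6, 7 and 8 reads in all libraries together, and the levels NK cells would bring were not measured. A smaller share of every non-CD8 cell type in KO also stays open, since the profile of the NK list over the libraries differed from those of the B cell (permutation p = 1e-04 over genes, the smallest the permutations can give) and myeloid lists (p = 0.0029) but not detectably from that of the CD4 list (p = 0.389), and this test takes genes as independent although those of the B cell list had an estimated correlation of 0.575. A trend with transcript length, GC content and expression level stays open as well, because its removal took the median to -0.40 with a bootstrap interval of -0.81 to -0.22 that includes -0.30, the bound set for it. A candidate explanation that was not tested is that KO mice hold fewer memory-like or innate-like CD8 T cells, which share these receptors, although the sort for naive cells named in the labels should remove memory-like cells as it should NK cells.

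Glycolysis genes were higher in KO, by a list median of 0.25. The same trend may account for part of this, since its removal left a median of 0.15 with a bootstrap interval of 0.10 to 0.23, which includes the bound of 0.12. KO 1, the library highest in ribosome biogenesis genes, was left out as another possible source, and the median was then 0.22 (interval 0.11 to 0.25) with the list still past camera at the preset correlation (all 6 libraries gave an adjusted p of 0.401 with an estimated one), which also leaves this open as a part of the shift. In the glycolysis list itself KO 2 was highest, with a median deviation of 0.21 against 0.17 in KO 1 and -0.0042 in KO 3. The shift was therefore uneven over the KO libraries. An effect of lower Txnip on glucose uptake, and through it on these genes, stays an untested hypothesis.

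Interferon-stimulated genes were higher in KO, by a list median of 0.46. A difference between the groups in the sex of the mice is argued against as the cause, since the number of libraries with high Xist differed by 0 (1 of 3 in each group), while an effect of sex that arises in KO mice alone was not tested. A trend with transcript length, GC content and expression level stays open, as its removal left a median of 0.33 with a bootstrap interval of 0.17 to 0.43 that includes the bound of 0.23. An effect of genotype of like size in every KO sample would place each KO library above each WT library only if it exceeded the spread between samples. KO 3 had a list median of -0.28 and the WT libraries ran from -0.26 to -0.08, so the groups were not separated. As this rests on 1 library it excludes nothing, and an exposure that differed between mice or wells could give such values too, which was not tested.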
